A study of Mus musculus with 20 samples.

How the data were processed

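Gene expression was measured by RNA sequencing in hearts of 20 mice with an intact (WT) or a targeted (KO) Sorbs2 gene. The sample labels name the tissue as left ventricle, while the series text and the extraction protocol name ventricular myocardium. Per the labels, RNA of integrity number above 9 went into stranded poly(A) libraries that were sequenced as 150 bp read pairs. The series text gives at least 40 M read pairs per sample and names DESeq2 for the authors' differential expression. Per the labels, the genome build was mm10; the aligner, the read counter, the gene annotation and the strand setting of the counting are not given in the sources used here.

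The authors deposited 2 tables of normalised counts per gene, one per age, and each was normalised on its own. The deposited unit is a signal: fractional, never negative values on a common scale within a table. The 6-month table lists 18657 genes in 14 libraries, and the 6-week table lists 17808 genes in 6 libraries, with 17243 genes in both. No column of values was left out. Totals of normalised counts ranged from 11359135 to 13670340 per library at 6 months and from 6705133 to 8240294 at 6 weeks. Within a library, the lowest values lay near multiples of one step. From that step, the reads counted per library came to about 9.6 to 14.1 M at 6 months and 6.1 to 9.2 M at 6 weeks. With a tolerance of 0.1 of a step, 87.6% to 93.4% of the low values were whole multiples at 6 months and 67.0% to 89.4% at 6 weeks, below the 95% set for recovering whole reads. The counts behind each value are therefore unknown, no counting intervals are given, and alternatives with edgeR and DESeq2, which need counts, were not run.

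Libraries were grouped by the genotype, age and treatment in their labels. The 6-week columns matched their group by name and could not be matched to single samples. The 6-week libraries were therefore analysed without pairing. At 6 months the replicate numbers did not pair the groups: after removal of group means, 7 of 13 pairs of like-numbered libraries correlated above 0.1 across genes (range -0.391 to 0.253), and in 3 of 13 the like-numbered library was the best match. The number was tried as a block all the same.

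Values were transformed as log2(value + 1). A gene was tested when its value was at least 10 in as many libraries as the smallest group of its table holds, 3 at 6 weeks and 4 at 6 months. The main test was limma 3.58.1 in R 4.3.3 (a linear model per gene with moderated variances and a mean-variance trend), two-sided. Adjusted p values followed Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The 3 groups at 6 months shared 1 model. Single measures were compared by exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 libraries. Knockout effects at the 2 ages were compared by the difference of their log2 changes over the combined standard error of both models, with Welch-Satterthwaite degrees of freedom. Knockout and vector effects at 6 months share the KO libraries. Their correlation across genes was therefore set beside 100 simulations without any effect, with noise independent between genes. It was also set beside all 10 splits of the KO libraries into parts of 2 and 3. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and plots.

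The rule for naming genes, the lists and the tests of the comparisons were fixed before the data were examined; genes and tests chosen later are marked as such where they are given. In each comparison the genes named were drawn from Sorbs2, Sorbs3, the 12 genes with the largest increase and the 12 with the largest decrease. The genes of largest change had an adjusted p under 0.05, a mean of at least 100 over the table, no overlap between the compared groups, and no predicted-gene, cDNA-clone or pseudogene symbol. In each list, up to 4 members of smallest p could be named. The 8 genes of smallest p were added among those changed in opposite directions by knockout and vector, and among those whose knockout effect differed between ages. The 35 lists cover cardiac pathways (calcium handling, microtubules, intercalated disc and intermediate filaments, sarcomere and Z-disc, actin and focal adhesion, stress and fetal genes, extracellular matrix, fatty acid oxidation, oxidative phosphorylation, glycolysis, ion channels), stress and housekeeping programmes (endoplasmic reticulum stress, chaperones, interferon response, cell cycle, circadian clock, immediate early genes), sex-linked genes, the chromosomal neighbours of Sorbs2, and markers of 16 cell or tissue types: cardiomyocytes, fibroblasts, endothelium, mural cells, macrophages, T and NK cells, B cells, neutrophils, erythroid cells, adipocytes, mesothelium, Schwann cells, atria, skeletal muscle, thymus and lung. Lists were tested with camera in limma at a preset correlation of 0.01 and again with the correlation estimated from the data, for lists with at least 3 tested members. Benjamini-Hochberg adjustment ran over the lists of a comparison. Counts "adjusted over the list alone" used the members of 1 list as the family of tests.

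Alternatives covered pseudocounts of 0.5 and 5, no filter and a stricter filter of 50, quantile normalisation, equal library totals, trimmed-mean factors recomputed from the deposited values, array weights, robust moderation, the replicate block, models of the 2 compared groups alone, and leaving out each replicate in turn. Further alternatives were chosen after seeing the data: the class of Xist or Y-linked expression as a covariate, Y-linked libraries alone, removal of each library's trend on GC content and transcript length, the leading within-group axis as a covariate, and leaving out the 2 KO libraries with the higher Sorbs2 values. Positions, GC content and transcript sequences came from a mouse gene annotation on the same build, in which 98.7% of the symbols were found.

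On simulated changes added to 200 of the genes of each comparison, the test recovered 50% of 2-fold and 80% of 4-fold changes at 6 weeks, with 3.7% false calls. At 6 months it recovered 73% and 88% for KO against WT with 4.2% false calls. The values were 60% and 91% with 6.2% false calls for the vector group against KO, and 57% and 93% with 6.8% false calls against WT. The simulated values were drawn independently for each gene and library. They lack the variation that genes shared within groups at 6 months, so these shares of false calls need not hold for the real libraries.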

Results

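RNA of 20 mouse hearts was sequenced in 5 groups. At 6 weeks of age there were 3 WT and 3 Sorbs2 KO mice, and at 6 months 5 WT mice, 5 KO mice and 4 KO mice given Sorbs2 back (KO+AAV). The last group had received, on postnatal day 2, an adeno-associated virus that carries Sorbs2 under the cardiomyocyte promoter of Tnnt2. Sorbs2 encodes an adaptor protein of the Z-disc and the actin cytoskeleton. The series is concerned with diastolic dysfunction after loss of Sorbs2, the cytoskeleton and calcium handling. Totals of normalised counts were 6790437 to 7414665 in KO and 6705133 to 8240294 in WT at 6 weeks, and 11359135 to 12222476 in KO, 12492381 to 13670340 in WT and 12024143 to 13041764 in KO+AAV at 6 months. The labels give no sex. Xist marked 1 of 3 libraries in each group at 6 weeks, and 2 of 5 WT, 0 of 5 KO and 2 of 4 KO+AAV libraries at 6 months; the others expressed Y-linked genes.

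Sorbs2 (chromosome 8, 45507788 to 45827906, mm10) was lower in KO hearts at both ages and above the KO level in all KO+AAV hearts. At 6 weeks its normalised count was 325 ± 45.3 in KO and 1717 ± 292 in WT (mean ± SD, n = 3 each), which is 18.9% of WT. At 6 months it was 1020.5 ± 625 in KO and 5040.2 ± 369 in WT (n = 5 each), or 20.2% of WT. KO replicates 1 and 5 held 1648 and 1755, and the other KO libraries 494 to 612. KO+AAV hearts averaged 11016 ± 6763 (n = 4), with replicates 1 and 2 at 4696 and 5753 and replicates 3 and 4 at 15690 and 17923. The log2 change of KO against WT was -2.39 at 6 weeks (adjusted p = 0.000552) and -2.52 at 6 months (adjusted p = 0.000543). It was 3.41 for KO+AAV against KO (adjusted p = 0.000383) and 0.89 for KO+AAV against WT (adjusted p = 0.281). Exact permutation p values were 0.1 at 6 weeks, the smallest that design allows, 0.00794 for KO against WT and for KO+AAV against KO at 6 months, and 0.0635 for KO+AAV against WT. The counts do not separate reads of the vector from those of the gene. Sorbs3 passed the test in none of the 4 comparisons (log2 0.34 and adjusted p = 0.431 for KO against WT at 6 months).

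**Figure D1:**
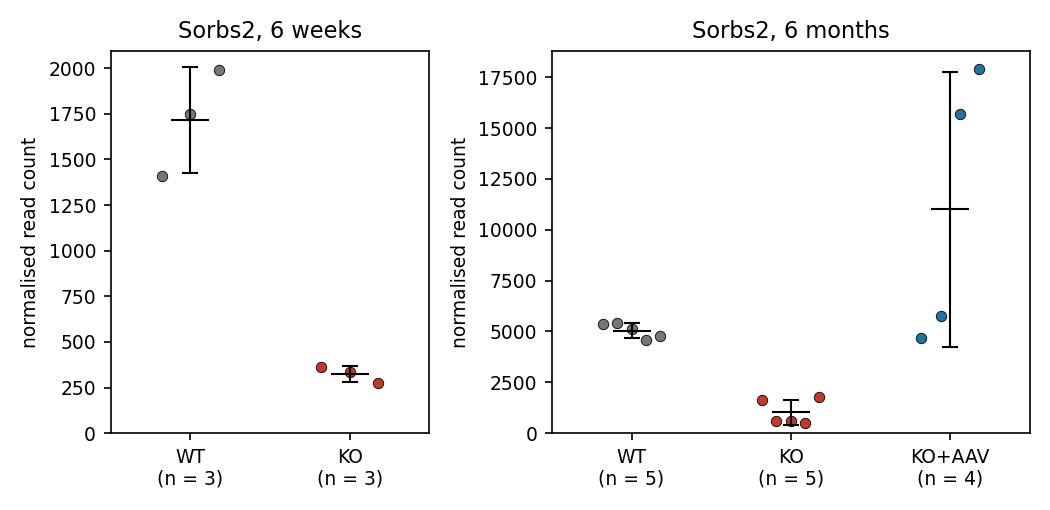
Normalised Sorbs2 counts (y axis, linear scale) in each library (points) of the 5 groups, with mean and SD. The 2 ages were normalised separately. KO libraries lie below every WT library of their age, and the 4 KO+AAV libraries range from 4696 to 17923.

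In young hearts, the comparison of KO with WT asks what loss of Sorbs2 does at 6 weeks of age. Thbs4, Myh7 and Casq1 were among the genes that rose in KO. Thbs4, a matricellular thrombospondin, went from 52.0 ± 18.6 in WT to 579.6 ± 169 in KO (n = 3 each), an 11.1-fold rise (log2 3.48, adjusted p = 0.000884). Myh7, the slow or beta myosin heavy chain, rose 9.90-fold from 1250.0 ± 449 to 14042 ± 10423 (adjusted p = 0.00791). Casq1, the calcium-binding calsequestrin of skeletal muscle, rose 6.13-fold from 178 ± 18.7 to 1096 ± 52.1 (adjusted p = 0.000122), and Mybpc2, the myosin-binding protein C of fast skeletal muscle, and Acta1, skeletal alpha-actin, rose by 2.25 and 2.01 on the log2 scale. Colq, which anchors acetylcholinesterase, fell (log2 -2.29).

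Of 13242 genes tested at 6 weeks, 78 changed, 50 up and 28 down. All 50 increases and 27 of the decreases were at least 2-fold, and 2045 genes had an unadjusted p under 0.05. The other named increases were Fkbp5, Fam107a and Ddit4, of which Fkbp5 and Ddit4 are known targets of the glucocorticoid receptor, the myelin gene Mbp, the clock output factor Hlf, Fam117b and Fibin, with log2 changes from 1.80 (Hlf) to 2.12 (Fkbp5). The other named decreases were Grip2, the mitochondrial uncoupling protein gene Ucp3, Lrtm1, Arhgef19, Rmdn1, Prune2, Mtl5, Asap3 and the muscle ribosomal protein gene Rpl3l, with log2 changes from -1.92 (Grip2) to -1.49 (Rpl3l). Myh7 shares 21.8% of its transcript sequence with Myh6. The count of 78 became 8 without WT6, 10 without KO3, 7 without KO4, 49 without WT1, 135 without WT16 and 154 without KO2. Of the 23 named genes other than Sorbs2, 4 (Arhgef19, Casq1, Colq and Thbs4) kept their call whichever library was left out; the others lost it without at least 1 of WT1, WT6, WT16, KO3 and KO4, with an adjusted p up to 0.209 (Mtl5).

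Matrix genes and several sets of cell type markers were shifted upwards at 6 weeks, mostly without members past the test over all genes. In the extracellular matrix list, 2 of 33 members rose (Thbs4 and Cilp, the latter by 1.57 on the log2 scale), none fell and 31 did not pass; adjusted over the list alone, 11 rose. The median was 0.57 and the camera adjusted p was 8.84e-10, with an adjusted p of 0.326 with an estimated correlation. Of 12 stress and fetal genes, 2 rose (Myh7 and Acta1; 3 adjusted over the list alone), with a camera adjusted p of 0.000712 and an adjusted p of 0.326 with an estimated correlation. Of 26 fatty acid oxidation genes, 1 fell (Ucp3, log2 -1.91; 1 adjusted over the list alone); the median was -0.45 and the camera adjusted p 0.000103, with an adjusted p of 0.326 with an estimated correlation. The 27 oxidative phosphorylation genes had a median of -0.31 and no member passed, with a camera adjusted p of 0.00212 and an adjusted p of 0.586 with an estimated correlation. Single members rose among ion channels (the potassium channel gene Kcna5, log2 1.59), interferon response genes (Bst2, 1.08), clock genes (Hlf, 1.80) and Schwann cell markers (Mbp, 1.96). Cilp, Kcna5 and Bst2 each lost the call without WT6, KO3 or KO4, and Cilp and Bst2 also without WT1 (adjusted p up to 0.135 for Cilp, 0.133 for Kcna5 and 0.168 for Bst2). All 17 lists that camera called at 6 weeks lost the call with an estimated correlation, with an adjusted p of at least 0.315. None of 26 calcium handling genes passed (median -0.14, camera adjusted p = 0.211), nor did any of 27 sarcomere genes (median -0.19, camera adjusted p = 0.239) or 5 skeletal muscle markers (median 0.06, camera adjusted p = 0.727). No member passed among 26 actin and focal adhesion genes (median 0.27, 3 up and 1 down adjusted over the list alone, camera adjusted p = 0.00614). The same held for 23 microtubule genes (median 0.21, 1 up and 2 down adjusted over the list alone, camera adjusted p = 0.0385). With an estimated correlation the adjusted p of both lists was 0.326. Fibroblast markers (10 tested, median 0.51) and endothelial markers (10 tested, median 0.39) had no member past the test over all genes, and 6 and 4 members were higher adjusted over the list alone. Medians were larger for 6 Schwann cell markers (1.14; 3 higher adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.315 with an estimated correlation), 4 mesothelial markers (1.59; 2 higher adjusted over the list alone, camera adjusted p = 0.00773) and 7 adipocyte markers (0.95; none adjusted over the list alone, camera adjusted p = 0.00459).

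Adult KO hearts were compared with WT at 6 months of age, the age at which hearts with returned Sorbs2 were also sampled. Matrix and stress genes stood above WT, and mitochondrial genes below. Vgll2, a cofactor of TEAD transcription factors, rose from 3.7 ± 1.8 in WT to 441 ± 233 in KO (n = 5 each), or 87.3-fold (adjusted p = 6.34e-07). Thbs4 rose 35.9-fold from 95.1 ± 33.9 to 3654 ± 1816 (adjusted p = 1.02e-06), and Cilp, a cartilage-type matrix protein made by fibroblasts, 27.8-fold from 86.5 ± 23.0 to 2412 ± 613 (adjusted p = 6.34e-07). Gdpd3, a phosphodiesterase of lysophospholipids, fell from 486 ± 182 to 4.0 ± 1.9, or 96.3-fold (adjusted p = 1.97e-07). Plekha7, a protein of adherens junctions, fell 11.1-fold from 359.7 ± 90.7 to 31.2 ± 6.0 (adjusted p = 1.02e-06).

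At 6 months, 2189 of 13419 genes differed between KO and WT (16.3%), 1091 up and 1098 down, and 561 of the increases and 334 of the decreases were at least 2-fold. The unadjusted p was under 0.05 for 3846 genes. Further named increases were the metalloproteinase genes Adamts8 (log2 5.53) and Adamts20 (5.33), the cholesterol transport gene Star (5.18), the matrix proteoglycan gene Fmod (5.16), Ildr2, Shisa3, the collagen gene Col12a1, the ryanodine receptor gene Ryr3 (4.37) and the Golgi GTPase gene Rab6b (4.09). Further named decreases were Abhd1 (-4.47), Lrrc4b (-3.29), Hddc3 (-3.19), Arc, the retinoic acid hydroxylase gene Cyp26b1, the potassium channel genes Kcnj14 (-2.39) and Kcnv2 (-2.38), the myosin light chain kinase gene Mylk4 and the cation transporter gene Slc22a3 (-2.26). All 23 named genes other than Sorbs2 kept their call under every alternative tried. Exons of genes on the opposite strand overlap 89.6% of Abhd1, 65.0% of Hddc3 and 10.6% to 13.6% of Gdpd3, Ildr2 and Adamts8, and Kcnj14 shares 31.1% of its transcript sequence with the predicted gene Gm5522. With libraries scaled to equal totals, 2428 genes differed, 1775 up and 653 down, so that 73.1% were increases in place of 49.8%, and the median of all genes shifted by 0.159 on the log2 scale. No KO library at 6 months carried Xist; among the Y-linked libraries alone, 1479 genes differed in the model of 3 groups and 1911 in a model of KO and WT alone.

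**Figure D2:**
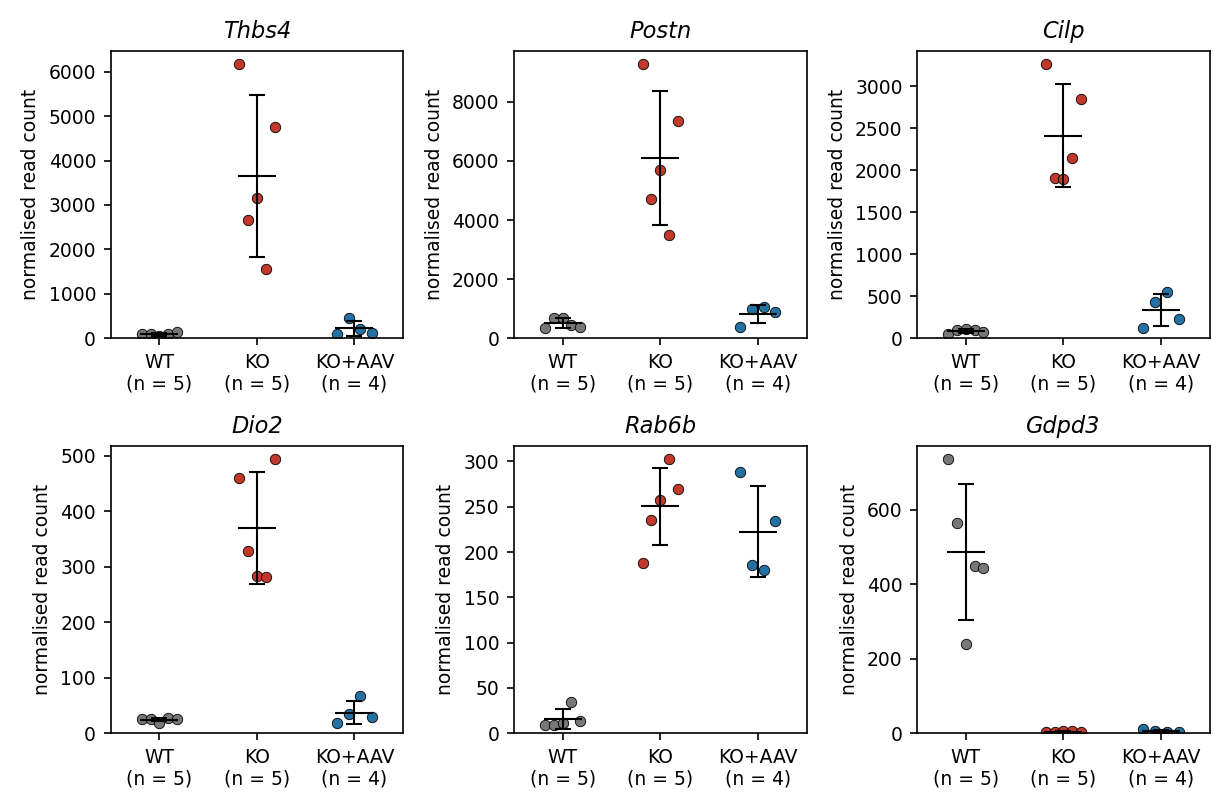
Normalised counts (y axes, linear scale) of Thbs4, Postn, Cilp, Dio2, Rab6b and Gdpd3 in each library (points) at 6 months, with mean and SD per group. Thbs4, Postn, Cilp and Dio2 in KO+AAV libraries lie below KO libraries, while Rab6b and Gdpd3 stay near the KO level.

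Extracellular matrix genes and load-responsive genes moved together in adult KO hearts. Of 33 matrix and fibrosis genes, 30 rose, none fell and 3 did not pass; adjusted over the list alone, 31 rose. Tgfb2, a growth factor that drives matrix production, rose from 129.5 ± 32.6 to 1676 ± 296 (log2 3.70), Postn, a protein of activated fibroblasts, by 3.57, and Comp, a cartilage matrix protein, by 3.71. The median was 1.23 and the camera adjusted p 1.42e-28, with an adjusted p of 0.0939 with an estimated correlation. Of 11 stress and fetal genes tested, 9 rose and none fell, also adjusted over the list alone (median 1.73, camera adjusted p = 4.38e-08, adjusted p = 0.118 with an estimated correlation). Nppa, atrial natriuretic peptide, rose from 7526 ± 1789.5 to 83351 ± 38430 (log2 3.36), Myh7 by 3.32, Ankrd1 by 2.66 and Fhl1 by 1.32. Fibroblast markers rose in 6 of 10 (7 adjusted over the list alone), among them Mfap5 (log2 1.94), and Col1a1 (1.52) and Col1a2 (1.31), which also stand in the matrix list (median 0.74, camera adjusted p = 0.000132, adjusted p = 0.239 with an estimated correlation).

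Genes of energy metabolism were lower in adult KO hearts. Of 27 nuclear genes of oxidative phosphorylation, 24 fell and none rose, also adjusted over the list alone, among them Uqcrc1 (log2 -0.94) and Cyc1 (-0.81). The median was -0.74 and the camera adjusted p 1e-16, with an adjusted p of 0.118 with an estimated correlation. Of 26 genes of fatty acid oxidation, 19 fell and none rose (21 fell adjusted over the list alone), led by the thiolase gene Acaa2, from 16256 ± 1531 to 5630.2 ± 1586 (log2 -1.57), Eci1 (-1.14) and Decr1 (-1.06); the median was -0.86 and the camera adjusted p 2.5e-12, with an adjusted p of 0.132 with an estimated correlation. Of 18 glycolysis genes, 2 rose and 7 fell (2 and 12 adjusted over the list alone). Eno3, the muscle enolase, fell by 1.76 on the log2 scale, the insulin-responsive glucose transporter gene Slc2a4 fell by 1.11 and Pfkp rose by 0.80 (median -0.44, camera adjusted p = 0.00023, adjusted p = 0.243 with an estimated correlation). Cardiomyocyte markers fell in 3 of 10 (6 adjusted over the list alone), namely Ckm (-1.57), Myh6 (-1.19) and Tnni3 (-0.97), with a median of -0.61, a camera adjusted p of 0.00264 and an adjusted p of 0.132 with an estimated correlation. Myh6 lost its call in 3 of 26 alternatives (no filter, quantile normalisation, and without the 2 KO libraries of higher Sorbs2; adjusted p up to 0.376). Tnni3 lost it in 4 of 26 (no filter, the class of Xist or Y-linked expression as a covariate, Y-linked libraries alone, and without WT 4 at 0.0529; adjusted p up to 0.109). The mean of the cardiomyocyte markers was lower in KO than in WT by log2 -0.63 (exact p = 0.00794), that of the fibroblast markers higher by 0.74 (exact p = 0.00794) and that of the endothelial markers lower by -0.21 (exact p = 0.0397).

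Calcium handling and cytoskeletal genes, with which the series is concerned, changed in part. Of 25 calcium handling genes tested at 6 months, 3 fell, none rose and 22 did not pass, with the same count adjusted over the list alone. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell from 20709 ± 1809.5 to 11209 ± 2403 (log2 -0.91, adjusted p = 0.00104). Cacnb2, an L-type channel subunit, fell by 0.70 and Asph, the junctin gene, by 0.35. Pln (phospholamban) had a log2 change of -0.73 with an adjusted p of 0.0608. The list had a median of -0.25 and a camera adjusted p of 0.0602. The call of Cacnb2 was lost in 8 of 26 alternatives, including those without WT 2, WT 3, KO 1 or KO 5 (adjusted p up to 0.0791), and that of Asph in 14 of 26, including those without WT 1, 2 or 4 or KO 1, 3, 4 or 5 (adjusted p up to 0.108). Of 23 microtubule genes, 5 rose and 2 fell, also adjusted over the list alone, with a median of 0.27 and a camera adjusted p of 0.0602. Map1a (log2 1.44), the neuronal beta-tubulin Tubb3 (2.20) and Map4 (0.56) rose and the alpha-tubulin Tuba4a fell (-0.89). Of 21 intercalated disc and intermediate filament genes, 5 rose and 1 fell, also adjusted over the list alone (median 0.08, camera adjusted p = 0.11). Xirp2, an actin-binding protein of the disc, rose from 9194 ± 3140.1 to 110397 ± 21986 (log2 3.64), and Nrap (1.09), Des (0.89) and Synm (0.86) also rose. Of 27 sarcomere and Z-disc genes, 2 rose, Synpo2l (2.56) and Flnc (0.76), and 4 fell (2 and 6 adjusted over the list alone), with a median of -0.24 and a camera adjusted p of 0.172. Among 26 actin and focal adhesion genes, Palld (0.43) and Actn1 (0.48) rose and Itgb1bp2 (-0.67) fell, also adjusted over the list alone (median 0.13, camera adjusted p = 0.154). The call of Palld was lost without KO 5 (adjusted p = 0.0633), and that of Actn1 without WT 4, KO 1 or KO 5 (adjusted p up to 0.0606).

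Ion channel genes fell in 7 of 24 and rose in 1 (9 and 2 adjusted over the list alone). Kcnip2 and Kcnd2, of the transient outward current, had log2 changes of -1.61 and -2.06 and Kcnj3 -1.52 (median -0.65, camera adjusted p = 0.00584, adjusted p = 0.341 with an estimated correlation). Interferon response genes rose in 9 of 18 (14 adjusted over the list alone), among them Ifit3 (1.39), Zbp1 (2.11) and Ifit2 (1.26), with a median of 0.85, a camera adjusted p of 3.64e-07 and an adjusted p of 0.216 with an estimated correlation. Cell cycle genes rose in 8 of 20 (10 adjusted over the list alone), among them Mcm6 (1.31), Mki67 (1.62) and Ccna2 (1.69), with a median of 0.90, a camera adjusted p of 1.88e-05 and an adjusted p of 0.339 with an estimated correlation. Schwann cell markers fell in 2 of 4, Gfra3 (-1.80) and Mbp (-1.11), also adjusted over the list alone (median -0.94, camera adjusted p = 0.00584, adjusted p = 0.132 with an estimated correlation). Among 12 mural cell markers, Cspg4 (1.20) rose and Acta2 (-1.26) and Abcc9 (-1.06) fell, with a camera adjusted p of 0.379; the call of Abcc9 was lost without WT 2, WT 3, KO 1 or KO 5 (adjusted p up to 0.0721). None of 10 endothelial markers passed (median -0.16, camera adjusted p = 0.117). Of 19 chromosomal neighbours of Sorbs2, Fat1 (1.40), Stox2 (0.64) and Enpp6 (0.94) rose and Slc25a4 (-0.89), the adenine nucleotide translocator of heart, fell, with a camera adjusted p of 0.236; the call of Enpp6 was lost without WT 1, WT 4 or KO 1 (adjusted p up to 0.067). In all, camera called 11 lists, and none kept the call with an estimated correlation.

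The remaining lists showed few changes in KO against WT at 6 months. Mthfd2 (log2 1.68), a mitochondrial folate enzyme induced by stress, rose and the chaperone-related genes Herpud1 (-0.90) and Hspa5 (-0.52) fell among 18 genes of endoplasmic reticulum stress (3 and 2 adjusted over the list alone, median -0.03, camera adjusted p = 0.914). Among 10 macrophage markers Fcgr1 rose (0.92; none adjusted over the list alone, median 0.32, camera adjusted p = 0.117). Among 6 neutrophil markers Mmp9 fell (-1.38, camera adjusted p = 0.38), and Tnni2 and Atp2a1 fell among 4 skeletal muscle markers (camera adjusted p = 0.217). None passed among 15 chaperones (camera adjusted p = 0.306), 14 clock genes (median -0.30, 0.379), 13 immediate early genes (median -0.75, 0.0602), 6 sex-linked genes (0.379), 4 B cell markers (0.216) or 6 erythroid markers (0.759). Calls were lost for Hspa5 without WT 2, WT 4, KO 1 or KO 5 (adjusted p up to 0.0663), Fcgr1 without WT 1, 2, 4 or 5 or KO 1, 2, 3 or 5 (up to 0.108), Mmp9 without WT 1, WT 2, WT 4 or KO 1 (up to 0.0728) and Atp2a1 without WT 1, 2 or 3 or KO 1, 2 or 5 (up to 0.0776). Nppa was the 1 of 3 atrial markers that rose (camera adjusted p = 0.267). The table held 2 tested markers each for T and NK cells, adipocytes and mesothelium and 1 each for thymus and lung, of which none passed.

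The difference between KO and WT was then compared between ages. At both ages KO hearts had more Thbs4, Casq1, Mybpc2, Acta1 and Myh7 (log2 3.31 at 6 weeks and 3.32 at 6 months) and the slow skeletal troponin gene Tnni1 (1.97 and 3.38), and less Rpl3l (-1.49 and -1.80) and Lrtm1 (-1.81 and -2.07). Tnni1 was chosen after its values were seen. Plekha7 was lower at 6 months (log2 -3.47) and not at 6 weeks (0.52), a difference of -3.99 (adjusted p = 7.8e-08). Gnal, a G-protein subunit, differed by 4.99, Rab6b by 3.65, the NAD pathway kinase Nmrk2 by 3.70, Myl1, a fast skeletal myosin light chain, by 3.27, Adamts8 by 4.47 and Comp by 3.37, each larger at 6 months. Prune2 fell at 6 weeks (-1.58) and rose at 6 months (1.17). Plekha7, Rab6b and Myl1 also stayed different from WT in KO+AAV hearts, with 8.4%, 4.4% and 26.8% of the KO change removed. Gnal, Nmrk2, Adamts8, Comp and Prune2 are not in that set. For Plekha7, Rab6b and Myl1, genetic background of the 6-month cohort cannot be told apart from age.

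Of 12709 genes tested at both ages, 15 rose at both (4 expected by chance, Fisher's exact p = 5.03e-06) and 7 fell at both (2.3 expected, Fisher's exact p = 0.00638). The 7 include Sorbs2, the targeted gene, whose fall followed from the design. Both p values treat genes as independent. Changes at both ages correlated at r = 0.245 and rho = 0.195 across genes, which are not independent replicates. Of 2064 genes called at 6 months, 1489 (72.1%) had the same sign at 6 weeks. The difference between ages itself passed for 518 genes, 253 of which had a higher log2 change at 6 months and 265 a lower one. The ages also differed in cohort, normalisation, estimated depth and atrial transcripts, so age cannot be told apart from these. Of the 4 genes called in opposite directions, Prune2 was lower at 6 weeks, and Mbp, Thrsp and Adh1, of which Thrsp and Adh1 were chosen after their values were seen, rose at 6 weeks and fell at 6 months. The count of 518 became 229 without WT6, 205 without KO3 and 259 without KO4 of the 6-week libraries. Nmrk2 overlaps exons of the opposite strand over 14.6% of its length, and Myl1 shares 21.4% of its sequence with the pseudogene Mylf-ps. The libraries also differed in atrial transcripts: in WT, Sln stood at 4528 ± 1017 at 6 weeks and 3.1 ± 4.0 at 6 months and Myl7 at 28190.5 ± 5297 and 12.4 ± 19.9, on scales normalised separately, and at 6 weeks atrial markers did not differ between KO and WT (7 tested, none passing, camera adjusted p = 0.727).

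The comparison of KO+AAV with KO asks what the vector that returns Sorbs2 to cardiomyocytes does in knockout hearts. Per the labels, no other group was injected. Effects of the virus and the injection therefore cannot be told apart from those of Sorbs2, here or in KO+AAV against WT. Matrix and stress genes that were high in KO hearts were lower with the vector. Thbs4 was 225 ± 165 in KO+AAV (n = 4) and 3654 ± 1816 in KO (n = 5), a 17.4-fold decrease (adjusted p = 0.000332). Postn fell 7.39-fold, from 6114 ± 2264 to 835 ± 302, and Dio2, which activates thyroid hormone, 10.6-fold, from 369 ± 101 to 36.8 ± 20.7 (adjusted p = 6.62e-05). Among genes that were low in KO hearts, Kcnv2 rose 4.14-fold to 276 ± 69.3 and Doc2g 2.26-fold to 3528 ± 238.

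In KO+AAV against KO, 1509 of 13419 genes differed, 745 up and 764 down, with 207 of the increases and 339 of the decreases at least 2-fold; 3975 had an unadjusted p under 0.05. Other named increases were Plxnb1, Mhrt, an antisense transcript of Myh7, the glycolysis regulator Pfkfb1, Ybx2, Myo5c, Lingo3, Slc36a2, the glycerol channel gene Aqp7, the transaminase gene Gpt and Adamts7, with log2 changes from 1.45 (Adamts7) to 1.87 (Plxnb1). Other named decreases were Col12a1, Adamts8, Fmod, Ryr3, the latent TGF-beta binding protein gene Ltbp2, the prolyl hydroxylase gene P3h2, Ildr2, Vgll2, Adamts20 and the cyclooxygenase gene Ptgs2, with log2 changes from -3.77 (Col12a1) to -3.08 (Ptgs2). The genes of smallest p among those changed in opposite directions also included Igfbp5 (-1.47), Cilp (-3.02), Col1a1 (-1.47) and Fn3k (1.20). Lingo3 lost its call without KO 4, KO 5 or KO+AAV 1 (adjusted p up to 0.0922), Adamts7 without KO+AAV 1 (0.0588) and Ptgs2 without KO+AAV 3 (0.0501), while the other 26 of 29 named genes besides Sorbs2 kept theirs whichever library was left out. Under all alternatives 23 of 29 kept it: Mhrt (adjusted p = 0.0502) and Ybx2 (0.0527) also lost it with the class of Xist or Y-linked expression as a covariate, and Pfkfb1 (0.0703) in Y-linked libraries alone. Doc2g shares 74.2% of its transcript sequence with Gm49405, Mhrt overlaps exons of Myh7 over 39.9% of its length, and P3h2 overlaps an opposite-strand gene over 28.4%. The count was 571 without KO+AAV 1 and 855 without KO 5, 542 with the class of Xist or Y-linked expression as a covariate and 332 in Y-linked libraries alone. With equal totals it was 1538, of which 521 rose and 1017 fell.

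Several lists, among them the matrix, stress and mitochondrial lists, moved opposite to the knockout effect. Of 33 matrix genes, 29 fell with the vector and none rose (32 fell adjusted over the list alone), with a median of -1.26, a camera adjusted p of 5.16e-29 and an adjusted p of 0.0894 with an estimated correlation. Of 11 stress genes, 9 fell (10 adjusted over the list alone), among them Fhl1 (log2 -1.49), Ctgf (-2.52), Myh7 (-2.46) and Nppa (-1.96), with a median of -1.63, a camera adjusted p of 2.91e-08 and an adjusted p of 0.159 with an estimated correlation. Of 27 oxidative phosphorylation genes, 19 rose and none fell (20 rose adjusted over the list alone), with Ndufa9 (0.79) and Cyc1 (0.73) among them (median 0.72, camera adjusted p = 5.31e-13, adjusted p = 0.193 with an estimated correlation). Of 26 fatty acid oxidation genes, 9 rose and none fell (10 rose adjusted over the list alone), with Acaa2 (1.33) and Eci1 (1.02) among them (median 0.43, camera adjusted p = 1.29e-06, adjusted p = 0.237 with an estimated correlation). Of 21 intercalated disc genes, 5 fell (6 adjusted over the list alone), led by Xirp2 (-2.54), with a camera adjusted p of 0.0011 and an adjusted p of 0.237 with an estimated correlation. Of 23 microtubule genes, Map1a (-1.42), Map4 and Tubb3 fell and Tuba4a rose, also adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.237 with an estimated correlation); Map1a kept its call under every alternative, while without KO+AAV 1 the adjusted p of Map4 was 0.051. Tubb3 lost its call without KO 1, KO 3, KO 5, KO+AAV 1 or KO+AAV 3 (adjusted p up to 0.133), and Tuba4a without KO 4, KO+AAV 1 or KO+AAV 3 (up to 0.0869). Of 25 calcium handling genes, 1 rose, Hrc (log2 0.72, adjusted p = 0.0136, 0.0579 without KO+AAV 1), also adjusted over the list alone (median -0.02, mean 0.06, camera adjusted p = 0.707). Fibroblast markers fell in 4 of 10 (6 adjusted over the list alone; camera adjusted p = 0.00109, adjusted p = 0.237 with an estimated correlation), and their mean was lower by -0.64 (exact p = 0.00794). The mean of cardiomyocyte markers was higher by 0.53 (exact p = 0.00794) and that of endothelial markers by 0.28 (exact p = 0.0159). Cell cycle genes (median -0.65, Mki67 down, none adjusted over the list alone, camera adjusted p = 0.00189, adjusted p = 0.434 with an estimated correlation) and Schwann cell markers (median 0.89, none past the test over all genes, 3 up adjusted over the list alone, camera adjusted p = 0.0332, adjusted p = 0.237 with an estimated correlation) also moved opposite to their shift in KO. Mki67 lost its call without KO 2, 3 or 5 or KO+AAV 1, 2 or 3 (adjusted p up to 0.154). Camera also called chaperones (median -0.36, adjusted p = 0.00703, adjusted p = 0.237 with an estimated correlation) and macrophage markers (median -0.44, adjusted p = 0.0199, adjusted p = 0.434 with an estimated correlation). Immediate early genes had negative medians in both comparisons (-0.75 in KO against WT and -0.94 here), with 1 of 13 members down here, also adjusted over the list alone (camera adjusted p = 0.00578, adjusted p = 0.523 with an estimated correlation). Interferon response genes, of which 9 of 18 rose in KO, had a median of -0.10 here with 1 member down, also adjusted over the list alone (camera adjusted p = 0.467). Of 26 actin and focal adhesion genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone). Their camera adjusted p was 0.0213, with an adjusted p of 0.315 with an estimated correlation. Ion channels (3 of 24 up, median 0.18, camera adjusted p = 0.17) and glycolysis (4 of 18 up and 1 down, median 0.19, camera adjusted p = 0.106), lower in KO, were not called here. Camera called 15 lists, and none kept the call with an estimated correlation.

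**Figure D3:**
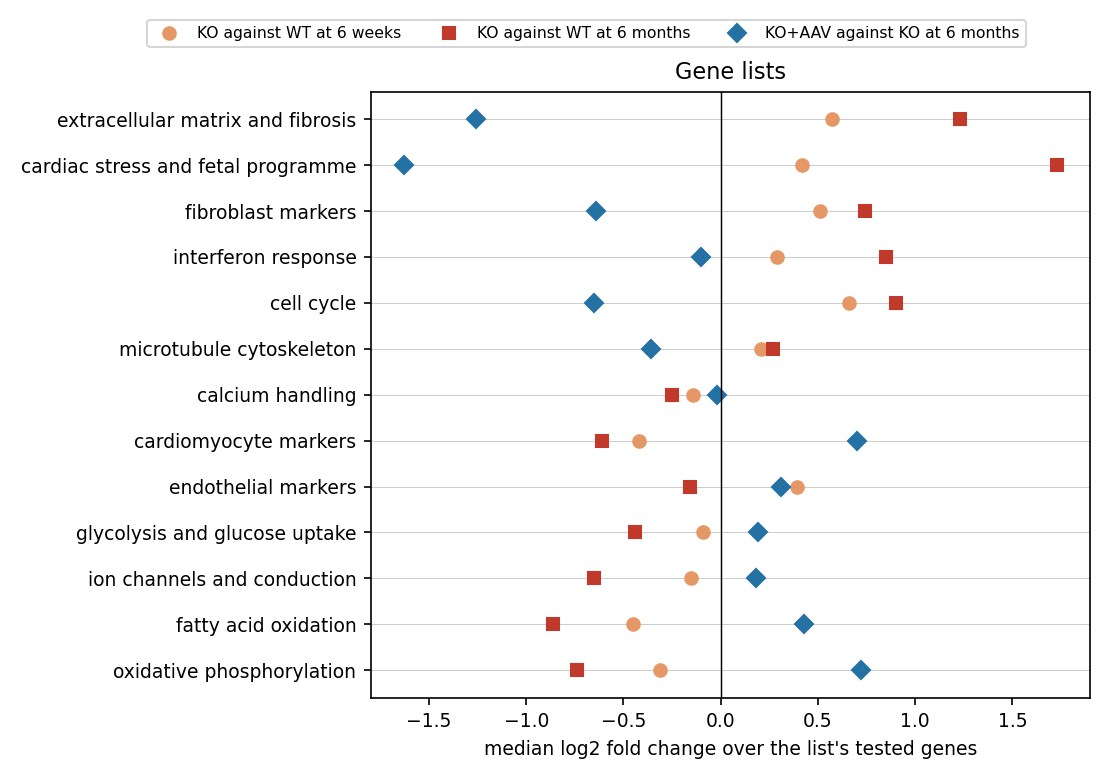
Median log2 change (x axis) of the tested members of 13 gene lists (y axis) in 3 comparisons (points by comparison). These are KO against WT at 6 weeks, KO against WT at 6 months and KO+AAV against KO at 6 months. In this order, the matrix list stands at 0.57, 1.23 and -1.26, and the oxidative phosphorylation list at -0.31, -0.74 and 0.72.

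Reversal was measured over all genes. Of 1091 genes that rose in KO, 492 fell with the vector (45.1%; 62.1 expected if independent), and of 1098 that fell, 484 rose (44.1%; 61.0 expected); 2 genes moved the same way in both. The log2 changes correlated at r = -0.626 across genes, where simulations without an effect, which share the KO libraries in the same way, gave -0.469 on average. Their noise was independent between genes, while 1 axis held 36.7% of the within-group variance of the real libraries. The gap between -0.626 and -0.469 therefore does not measure reversal. With separate KO libraries in each comparison, the median over the splits was -0.543 (-0.610 to -0.216). With genes chosen on part of the libraries and measured in the rest, 61.1% of the KO change was removed (median over 100 splits, range 44.2% to 143.2%). Along the KO change, scaled from 0 for WT to 100 for KO and measured in each library with genes called without it, WT libraries stood at 9.0 ± 8.7, KO libraries at 93.1 ± 14.4 and KO+AAV libraries at 37.8 ± 13 (SD). KO+AAV replicate 1, with the lowest Sorbs2 of its group, stood at 19.6, and the other KO+AAV libraries at 37.1 to 47.3. The count of genes moved in opposite directions was 976, and 514 without KO+AAV 1, 591 without KO 5, and 469 with the class of Xist or Y-linked expression as a covariate.

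**Figure D4:**
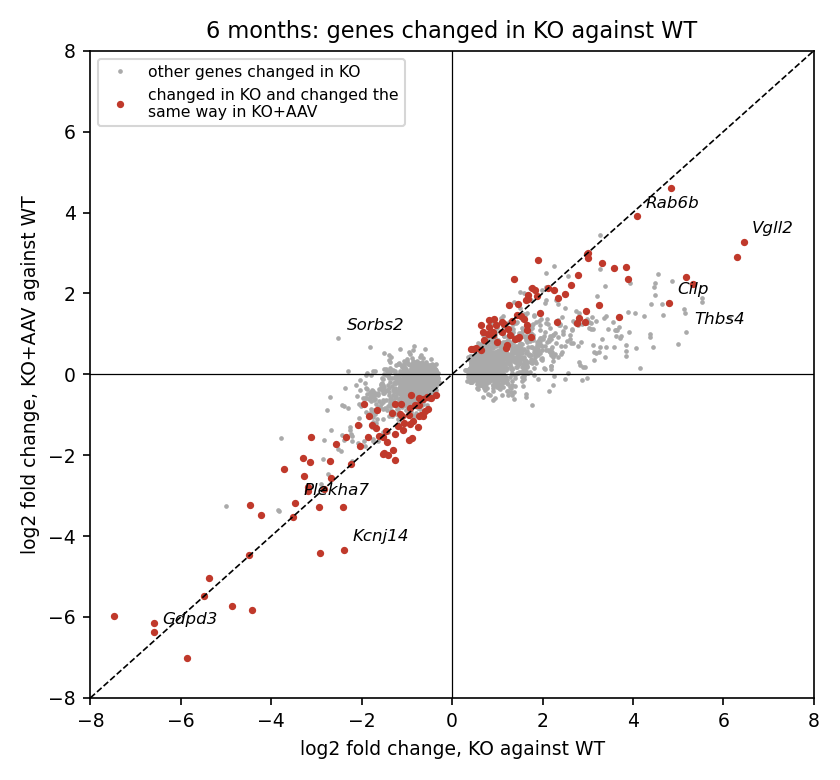
Log2 change of KO against WT (x axis) and of KO+AAV against WT (y axis) for the 2189 genes changed in KO at 6 months (points); the dashed line marks equal changes. Red points are the 146 genes also changed in the same direction in KO+AAV.

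What stayed different from WT after Sorbs2 was returned was asked with KO+AAV against WT. Rab6b was 222 ± 50.4 in KO+AAV (n = 4) and 15.6 ± 10.9 in WT (n = 5), 15.1-fold higher (adjusted p = 4.08e-06) and close to the 250.4 ± 42.7 of KO. Gdpd3 was 5.4 ± 3.9 against 486 ± 182, 83.0-fold lower (adjusted p = 1.53e-06), and Plekha7 41.1 ± 17.8 against 359.7 ± 90.7, 9.06-fold lower (adjusted p = 1.21e-05). Myl1 stayed 6.16-fold and Vgll2 9.72-fold higher, and Kcnj14 was 20.2-fold lower than in WT.

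In this comparison 178 of 13419 genes differed, 82 up and 96 down, with 62 of the increases and 73 of the decreases at least 2-fold; 2454 had an unadjusted p under 0.05. Of these, 146 had changed in the same direction in KO against WT, 70 up and 76 down, and none in the opposite direction. Both comparisons share the WT libraries, which by itself favours calls in the same direction. Their log2 changes correlated at 0.555 across genes, where simulations without an effect gave 0.474 on average. The simulated noise was independent between genes, unlike that of the libraries, so the gap between these values decides nothing. With separate WT libraries the median over the splits was 0.425 (0.08 to 0.623). Other named increases were Hrasls (log2 2.45), the T-type calcium channel gene Cacna1h (1.97), Cilp (1.77), the lipocalin gene Apod (1.57), Mfap4, Zfp157, Lrrcc1 (1.30), Shisa4 and the G-protein gene Gnao1 (1.26). Other named decreases were Arc (-3.29), Abhd1 (-3.24), the nuclear receptor gene Nr4a3 (-2.98), Hddc3 (-2.79), Lrrc4b, Gcnt1 (-1.95), Rhobtb3 (-1.88) and the butyrylcholinesterase gene Bche (-1.57). Of 24 named genes, 15 kept the call whichever library was left out, and 9 lost it without at least 1. Among these were Bche (KO+AAV 1, adjusted p = 0.0556), Cacna1h (KO+AAV 1, 2 or 3, up to 0.0616), Cilp (WT 1, KO+AAV 2 or 3, up to 0.0596), Lrrc4b (WT 1 or 2, KO+AAV 2 or 3, up to 0.0597), Shisa4 (WT 3, KO+AAV 2 or 3, up to 0.0781), Zfp157 (WT 2 or 4, KO+AAV 1, 2 or 3, up to 0.0795), Nr4a3 (WT 1, 2 or 4, KO+AAV 1, 3 or 4, up to 0.117) and Mfap4 (WT 1, 2, 3 or 4, KO+AAV 2, 3 or 4, up to 0.12). The count was 109 without WT 1, 115 without WT 2, 472 without WT 5, 115 without KO+AAV 1 and 108 without KO+AAV 3, 36 in Y-linked libraries alone and 101 in a model of the 2 groups alone. With equal totals it was 240, of which 158 rose and 82 fell.

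The interferon list stood above WT in KO+AAV hearts and the immediate early list below. Of 18 interferon response genes, 1 rose, Ifit3 (log2 0.88), and 10 rose adjusted over the list alone (median 0.72, camera adjusted p = 2.76e-08, adjusted p = 0.486 with an estimated correlation). The call of Ifit3 was lost in 13 of 24 alternatives, including those without WT 1, 2, 3 or 4 or KO+AAV 1, 3 or 4 (adjusted p up to 0.102). Of 13 immediate early genes, 1 fell, Btg2 (-1.84), and 11 fell adjusted over the list alone (median -1.84, camera adjusted p = 2.76e-08, adjusted p = 0.814 with an estimated correlation). The mean log2 value of these genes was 7.67 in KO+AAV replicate 3 and 7.78 in replicate 4, against 9.97 to 11.94 in the other libraries at 6 months, and the call of Btg2 was lost without KO+AAV 3, KO+AAV 4 or WT 1, 2, 3 or 4 (adjusted p up to 0.099). Of 33 matrix genes, Cilp and Tgfb2 (1.43) were higher and Thbs1 (-2.77) lower, also adjusted over the list alone, with a median of 0.08 and a camera adjusted p of 0.403. The call of Tgfb2 was lost without WT 1, WT 3, WT 4, KO+AAV 2 or KO+AAV 3 (adjusted p up to 0.109) and that of Thbs1 without WT 1, WT 2, WT 4, KO+AAV 1, KO+AAV 3 or KO+AAV 4 (up to 0.129). None of 27 oxidative phosphorylation genes passed (median -0.11, camera adjusted p = 0.192), and none of 26 fatty acid oxidation genes (median -0.29, camera adjusted p = 0.0156, adjusted p = 0.814 with an estimated correlation). Of 25 calcium handling genes, Asph fell (-0.50), also adjusted over the list alone (camera adjusted p = 0.108); it lost its call in 16 of 24 alternatives, including those without WT 1, 2, 3 or 4 or any 1 of the KO+AAV libraries (adjusted p up to 0.121). Camera called 5 lists in all, the others being glycolysis (median -0.28, adjusted p = 0.0196) and B cell markers (median 0.86, adjusted p = 0.0362), and none kept the call with an estimated correlation.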

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

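The tests of sex, cell share, genetic background, shared sequence, reversal left unfinished, GC content and length, and nuclear RNA in this part were chosen after the results were seen; the counts of other splits were planned. In 1 library of a group, a gene lay far from the other libraries of its group, measured by the gap to the nearest library over the range of the group. Chance gives about 1 in 20 groups, or 9.8 of the 195 groups tested, and 13 were found. They were Rab6b in WT 4 (0.822; 34.9 against 8.78 to 13.4), Abhd1 in WT 1 (0.736; high), Cyp26b1 in WT 4 (0.726; 956 against 53.2 to 300.4), Mylk4 in WT 2 (0.734; high), Plxnb1 in WT 5 (0.781; high), Ptgs2 in WT 2 (0.83; high), Nr4a3 in WT 2 (0.783; high) and Dio2 in WT 3 (0.748; low). In KO they were Pfkfb1 in KO 5 (0.755; low) and Cacna1h in KO 3 (0.77; high), and in KO+AAV replicate 1 Pfkfb1 (0.948; 387.5 against 90.0 to 106), Ltbp2 (0.886; low) and Gcnt1 (0.918; low). The knockout effect differed between the ages by a test of the difference for 518 genes. Of 100 splits within each table, 1, the real one, gave as many (highest other 94). Those splits remove the knockout effect at both ages, so they cannot show whether it was equal at both. The cause was not tested.

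The knockout effect at 6 months, 2189 genes with the matrix and stress genes up and the metabolic genes down, was set against the sex of the animals and a lower share of cardiomyocytes. Only 1 of 100 splits of the WT and KO libraries, the real one, gave as many genes (highest other 949, for WT 1, 4, 5 with KO 1, 5), so chance is excluded for the genes; for the 11 lists called by camera it is not, since 24 of 100 splits gave as many (highest other 16). Sex is argued against as the whole cause, since among the Y-linked libraries alone 1911 genes differed in a model of KO and WT (1479 with KO+AAV in the model), 1 of 56 splits gave as many (highest other 1) and the matrix median stayed at 1.23. A lower share of cardiomyocytes as the only change would raise the markers of all other cells alike. Instead, the fibroblast minus endothelial difference rose by 0.95 (exact p = 0.00794) while the endothelial mean stood at -0.21. These shifts were seen before the test was chosen, and the fibroblast markers Col1a1, Col1a2 and Lum are also matrix genes of the pattern. The values do not exclude a lower share of cardiomyocytes together with more fibroblasts. A response to the loss of Sorbs2, with more fibroblasts or more matrix expression per fibroblast, may underlie the pattern. This is a hypothesis drawn from the same data and was not itself tested.

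Of the 178 genes that differed from WT in KO+AAV hearts, 146 had changed the same way in KO, in a comparison that shares the WT libraries, among them Gdpd3, Rab6b and Plekha7. A count of 178 or more came from 3 of 100 splits, the real one included, a share under 0.05. The highest other was 2167, for WT 5 with KO+AAV 1, 2 and 3, and the next 1977, for WT 4 and 5 with KO+AAV 1 and 2. These splits point to a structure of the samples, so the count of genes by itself does not exclude chance. Nor is chance excluded for the 5 lists called (53 of 100 splits, highest other 13). Genetic background may contribute, since 27 pairs of the 146 genes lay within 1 Mb of each other (17.6 expected, p = 0.0432 by permutation over 10000 random sets). Chromosome 8, which carries Sorbs2, held 10 of the genes (7.6 expected, 95th percentile 12), no excess on that chromosome. Other chromosomes were not tested for an excess. Of the largest decreases named in KO, Gdpd3, Plekha7, Lrrc4b, Hddc3 and Kcnj14 lie on chromosome 7. Abhd1, Arc, Cyp26b1, Kcnv2, Mylk4 and Slc22a3 lie on others. A background common to both cohorts is argued against, since at 6 weeks 73 of the 127 tested had the same sign and 1 was called. The median change in that direction was 0.05 at 6 weeks against 1.65 at 6 months. Reads shared between near-identical copies may contribute too, since 25 of 144 genes shared at least 20% of their transcript with another gene (9.4 expected; permutation p = 0.0001, the smallest possible). Reversal left unfinished by the vector cannot be told apart from these, as the share of the KO change removed in libraries left out of the choice of genes had a median of 5.9% and ranged from -13% to 43.3% over 50 splits.

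Within groups at 6 months, 1 axis held 36.7% of the variance, above the 11.2% that was the highest of 100 simulations of independent noise, with WT 4 and 5, KO 1 and 5 and KO+AAV 1 and 2 on 1 side. GC content and transcript length are argued against, as the axis kept 35.2% after their trends were removed, and so is sex, as the axis held 42.7% among the Y-linked libraries alone (permutation p = 0.23 for a difference between the classes); with the estimated depth of the libraries removed it held 37.7%. A larger share of nuclear or unspliced RNA in those libraries may contribute, since 99 long intergenic non-coding RNAs loaded at -0.56 on average (permutation p = 0.0001, the smallest possible), and Malat1 ranged from 20832 to 91026. For KO+AAV against KO, 2 of 100 splits, the real one included, called as many as 1509 genes, a share under 0.05. The split of KO 1 and 5 with KO+AAV 1 and 2 from the others, which follows the axis, called 2152. The count of genes by itself therefore does not exclude chance. Nor is chance excluded for the 15 lists called (5 of 100 splits, highest other 17). For the 976 genes called in opposite directions, 1 of 100 splits, the real one, gave as many (highest other 0). Those splits remove the knockout effect too, so they exclude only that no group differed. A biological cause of the axis was not tested.

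At 6 weeks the 10 splits of 3 against 3 libraries are too few for a share under 0.05: the real split called 78 genes and the highest other 3, and 17 lists and the highest other 9 (1 of 10 in each).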

How the results depend on the processing

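The covariate of Xist or Y-linked expression, the Y-linked libraries alone, the axis within groups as a covariate, the KO libraries of lower Sorbs2 alone, and leaving out libraries for the difference between ages were chosen after seeing the data. No list or named gene called in the main analysis changed direction in the alternatives run. Directions were not compared for those that passed in neither. In KO against WT and KO+AAV against WT at 6 months, decreases outnumbered increases in the main analysis and increases outnumbered decreases with equal totals. Of 224 alternatives for the main results 181 kept the count within 1.5 times or the value within its spread and 43 did not; of 484 for lists 418 kept their side of the threshold, 58 lost it and 8 gained it; and of 6030 for named genes 5491 kept it, 534 lost it and 5 gained it. For KO against WT at 6 weeks (78 genes) the count was 36 with equal totals (27 up, 9 down), 2371 with array weights, 189 with the covariate, 505 in Y-linked libraries, and 7 (without KO4) to 154 (without KO2) leaving out 1 library, with 49 without WT1, 8 without WT6, 135 without WT16 and 10 without KO3. At 6 months KO against WT (2189) gave 4031 with the axis and 1381 without the 2 KO libraries of higher Sorbs2, where fewer libraries were used. KO+AAV against KO (1509) gave 3683 with array weights, 542 with the covariate, 332 in Y-linked libraries, 4659 with the axis, and 571 (without KO+AAV 1) to 1816 (without KO 1), with 855 without KO 5. KO+AAV against WT (178) gave 868 with array weights, 36 in Y-linked libraries, 3109 with the axis, 101 from the 2 groups alone, and 108 (without KO+AAV 3) to 472 (without WT 5), with 109 without WT 1 and 115 without WT 2 or without KO+AAV 1. With the replicate block the counts were 2071, 1764 and 183. The difference between ages (518) ranged from 205 (without KO3) to 585 (without WT 5), with 229 without WT6 and 259 without KO4, and the correlation of the ages (0.245) was 0.271 at a mean of at least 100. The genes called in opposite directions (976) numbered 469 with the covariate and 514 (without KO+AAV 1) to 1099 (without WT 2), with 591 without KO 5; their correlation (-0.626) was -0.543 with KO libraries split, and -0.697 (without WT 2) to -0.533 (without WT 5), with -0.564 without KO+AAV 4. With an estimated correlation 0 of 17, 0 of 11, 0 of 15 and 0 of 5 lists were called, and 2 of the 5 with quantile normalisation. Except where fewer libraries were used, the cause was not tested. With equal totals the counts for the 3 comparisons at 6 months stayed within 1.5 times, with the up and down shares given in the report. Alternatives that need counts were not run, as whole reads could not be recovered, and at 6 weeks the test recovered 50% of simulated 2-fold changes.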

Other observations

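Among the genes called in the same direction at both ages were Fibin (log2 1.85 at 6 weeks and 2.43 at 6 months), Igfbp7 (1.37 and 1.18), Emp1 (1.34 and 1.30) and C1qtnf6 (1.39 and 1.84), all higher in KO, and Pfkfb1 (-2.29 and -1.71), Crhr2 (-1.36 and -1.19) and Asb14 (-1.33 and -0.77), all lower. Igfbp7, Emp1, C1qtnf6, Crhr2 and Asb14 were chosen after their values were seen. Of the 78 genes called at 6 weeks, 47 had the same sign at 6 months.

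Atrial transcripts stood high at 6 weeks in both genotypes. In WT, Myl4 was 23543 ± 10273 and Mybphl 1799.6 ± 324 at 6 weeks, against 54.5 ± 26.1 and 8.2 ± 6.6 at 6 months, and Nppa 87014 ± 29816 against 7526 ± 1789.5, on scales normalised separately. In KO at 6 weeks, Myl4 was 21538 ± 5952 and Mybphl 1992 ± 499. With an estimated correlation, the 6-week shifts of adipocyte and mesothelial markers had adjusted p values of 0.377 and 0.326. Clock genes had a median of 0.63 at 6 weeks (6 up and 2 down adjusted over the list alone, camera adjusted p = 0.00659, adjusted p = 0.326 with an estimated correlation). The precursor ribosomal transcript Rn45s took 1.94% to 4.98% of the values at 6 weeks and 0.2% to 0.44% at 6 months.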
